A study of Caenorhabditis elegans with 2 samples.

How the data were processed

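Chromatin immunoprecipitation followed by sequencing was performed on whole L4 larvae of a Caenorhabditis elegans strain in which genome editing had added TY1, EGFP and FLAG tags to zfp-3. Per the labels, the animals were 48 h old and had been synchronized by starving hatchlings after bleaching, chromatin was sonicated to fragments of 200 to 800 bp, and an antibody against GFP was used. The 2 samples are biological replicates 1 and 2 of 1 group, and GEO's labels gave the replicate numbers. The labels name a possible control experiment, which was not used here.

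The deposited files are peak lists on the ce11 build. Per the file headers and notes deposited with them, a list of a single library was made from that library's alignments and a list of the series from both libraries, each with a further file common to all. Peaks had been ranked by the irreproducible discovery rate (IDR), and each thresholded list is a subset of a ranked one. The signal in these lists is the authors' deposited strength of each peak; its scale is not given in the sources used here, so signals were compared within a list only. The score in these lists is the authors' deposited scaled IDR, and every thresholded peak had a score of at least 830, which is a global IDR of at most 0.01. The aligner, the peak caller and their versions are not given in the sources used here. Columns for p and q values were not used.

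The conservative thresholded list of the series, with 2010 peaks, was the main list. It was chosen because, by its name, it holds peaks that pass IDR between the 2 replicates. The choice of lists, tests, gene lists and alternatives was made before the data were examined. Genes, exons and 5′ ends were taken from Ensembl release 115 for the WBcel235 assembly, whose chromosome lengths match ce11, with 19973 protein-coding and 46890 nuclear genes. A gene counted as bound when a summit lay within 1000 bp upstream to 200 bp downstream of its 5′ end.

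Shares of summits in promoter windows, exons, introns, noncoding RNA genes and intergenic sequence were compared with 100000 circular shifts of the summits along each chromosome (one-sided). The overlap of the replicates, by at least 1 bp, was tested the same way, and their signals were compared over one-to-one pairs of overlapping peaks by Spearman's rho and Pearson's r with 100000 permuted pairings. Peaks per chromosome and in the outer against the central parts were compared with base pairs by two-sided exact binomial tests. The 45 gene lists, 37 of protein-coding genes and 8 of RNA biotypes and pseudogenes, were tested by two-sided Fisher exact tests against all nuclear protein-coding genes or all nuclear genes. Their 95% intervals are Woolf intervals with 0.5 added to each cell. For each 6-mer, both strands taken as 1, presence within 50 bp of the summit was compared with presence in 101 bp centred 400 bp to one side of the same summit, the side drawn per peak with a fixed seed, by an exact McNemar test. Median log10 signals of promoter and other peaks were compared by a two-sided permutation test with 100000 resamples. Within each family, p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The smallest permutation p is 1e-05. Intervals of shares are exact binomial 95% intervals, and p-values over peaks or genes describe these 2 libraries, since peaks and neighbouring genes are not independent replicates.

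The rule for named genes was to name the genes at the 20 strongest peaks of the main list, zfp-3, and up to 4 bound members with the highest signal of each gene list; for a strong peak outside promoter windows the nearest gene was named, and where windows overlapped the gene with the nearest 5′ end. The 5 6-mers with the smallest p were named. The text gives part of the named list members, and other names that fall outside the rule are said to be chosen after their values were seen. This holds for F44E5.5, rpl-7A, rpl-12, eef-1A.1, rps-20, ekl-4, him-4 and AGACGCAG in the report, which share a site with a named item or contain it.

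Alternatives were the list of each library alone, the other thresholded list of the series, the 1005 and the 500 peaks with the highest signal, other promoter windows, other definitions of overlap, expected shares from gene numbers, merged neighbouring summits, other ways to assign genes, and other windows, flanks and lengths for k-mers. The authors' threshold was already an IDR of 0.01, so the 1005 strongest peaks stood in for a stricter threshold. Leaving out the peaks within 100 bp of a tRNA gene was added after seeing the data. For base composition, a 6-mer was chosen on chromosomes I to III and its ratio on IV, V and X was given a 95% interval from 10000 bootstraps of the peaks.

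The shift, overlap, gene list, k-mer and median tests were tested on simulated data. Simulated summits without preference gave p of at most 0.05 in 5.50% of 200 sets, unrelated replicate lists in 5.00%, and random bound genes gave a list past the threshold in 3.50%. The random genes were drawn without regard to position and tested on the 37 protein-coding lists only. The rate therefore does not cover genes that share a summit or the other 8 lists. With 45.0% of 2010 simulated summits in promoter windows, 45.7% were found there, and with 59.9% of 931 simulated peaks shared, 60.5% were found shared. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.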

Results

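The binding of ZFP-3, a zinc finger protein of Caenorhabditis elegans, was mapped in whole L4 larvae aged 48 h. The animals carried the endogenous zfp-3 gene on chromosome X fused to EGFP and epitope tags, and chromatin was immunoprecipitated with an antibody against GFP and sequenced. There was 1 group with 2 biological replicates and no other condition, so the design asks where the tagged protein was found and whether the replicates gave the same sites. The authors' conservative list, made from both libraries, held 2010 peaks with a median width of 336 bp. Together these peaks covered 632 kb, or 0.630% of the 6 nuclear chromosomes of the ce11 build. The lists of the single libraries held 931 peaks for replicate 1 and 933 for replicate 2. A further list of the series held 1458 peaks. Read depth per library is unknown from these lists, and the signal of a peak, as the authors deposited it, can be compared within a list only. A gene is called bound below where a peak summit lay within 1000 bp upstream to 200 bp downstream of its annotated 5′ end. Of the summits in such windows of protein-coding genes, 577 lay in 1 window and 187 in several. A gene named below can therefore share its summit with a neighbour that is not named.

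The strongest site of the main list lay upstream of rpl-3, which encodes a protein of the large ribosomal subunit. Its peak on chromosome III (3867071 to 3867724) had a signal of 778 and a summit at -282 bp from the 5′ end of rpl-3, in intergenic sequence. The 41 bp centred on that summit read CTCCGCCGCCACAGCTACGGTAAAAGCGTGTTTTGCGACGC in the reference genome. Of the 20 strongest peaks, 12 had the summit in the promoter window of a protein-coding gene and 8 did not. F44E5.4, an Hsp70 family gene, shared its summit with its divergent neighbour F44E5.5 on chromosome II (11759306 to 11759663, signal 648). tasp-1 on chromosome III followed with a signal of 613 and a summit 56 bp upstream of its 5′ end. mog-4, a helicase gene needed for the sperm to oocyte switch of the germ line, had a signal of 578, and cdc-48.1, which encodes an AAA ATPase of protein degradation, had 554.

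The other strongest sites included rpa-2, rpl-15, ego-1, his-37 and cbp-1. rpa-2, which encodes a subunit of the single-stranded DNA binding protein RPA, had a signal of 519 on chromosome I (4769531 to 4769751), and rpl-15 had 514 on chromosome IV. fil-2 had a signal of 460.0, Y17G9B.5 had 447 at a summit shared with rpl-20, and ego-1, which encodes an RNA-dependent RNA polymerase of germline RNA interference, had 425. The histone gene his-37 had a signal of 417 on chromosome V (9546912 to 9547113), and cbp-1, which encodes a histone acetyltransferase, had 413 at a summit at -907 bp from its 5′ end. Among the 8 strong peaks outside promoter windows, 2 lay on chromosome IV beside K08F11.7, a noncoding RNA gene, and K08F11.6, a pseudogene, with signals of 734 and 659. The pseudogene K07D4.1 (549), Y94H6A.10 (456) and the noncoding RNA gene F44E5.16 (433) were the nearest genes to 3 further intergenic summits. The summits at dos-3 (452) and T28F4.4 (412) lay in coding sequence, and the last of the 20 lay inside the noncoding RNA gene linc-128 (404).

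These strongest sites were found in both replicates: all 20 overlapped a thresholded peak of replicate 1 and one of replicate 2. The main list was chosen because its name marks peaks that pass IDR between the replicates. The overlap of its strongest peaks with both libraries is therefore no independent support. Of 125 named members of gene lists, 79 overlapped a peak in both single-library lists, 23 in 1 of them and 23 in neither. Over all sites, 549 of the 931 peaks of replicate 1 overlapped a peak of replicate 2 by at least 1 bp, a share of 59.0% (exact 95% interval 55.7 to 62.1%). In the other direction 544 of 933 peaks did, or 58.3% (exact 95% interval 55.1 to 61.5%). Circular shifts of the peaks along each chromosome gave a mean of 4.61 shared peaks and a highest value of 106, and the one-sided permutation p was 1e-05, the smallest that 100000 shifts can give. Peaks found in 1 replicate only were weaker, with a median signal of 53.6 against 73.7 for shared peaks in replicate 1 and of 49.3 against 70.7 in replicate 2. Across 516 pairs of shared peaks, the signals of the replicates had a Spearman rho of 0.732 and a Pearson r of 0.882, each with a permutation p of 1e-05. Over 18179 overlapping pairs of the ranked lists, without the threshold, rho was 0.402 and r was 0.804. These values are across peaks, which are not independent replicates. The single-library and series lists differed in size, and 918 of the 2010 peaks of the main list, 45.7%, overlapped a thresholded peak of neither library alone.

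**Figure D1:**
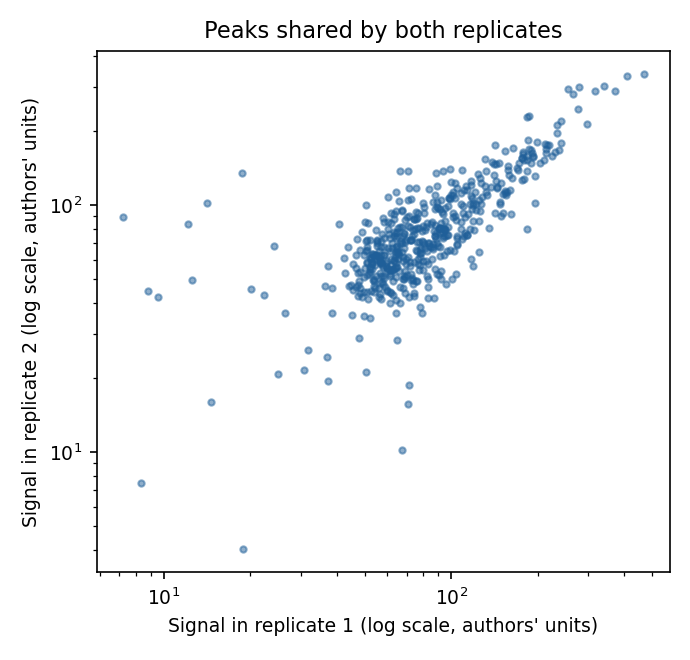
Signal of the 516 peaks shared by the thresholded lists of replicate 1 (horizontal axis) and replicate 2 (vertical axis), both on log scales in the authors' units. Each point is 1 peak, and the Spearman rho across peaks was 0.732.

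Summits gathered at promoters of protein-coding genes and inside noncoding RNA genes, and were fewer in exons and introns than shifted summits were. Promoter windows held 764 of the 2010 summits, or 38.01% (exact 95% interval 35.9 to 40.2%), against a mean of 21.2% in circular shifts, a ratio of 1.79. Noncoding RNA genes held 249 summits, 12.4% against 1.75%, a ratio of 7.07. Intergenic sequence held 45.1% against 32.99%. Exons of protein-coding genes held 23.8% of summits against 29.5% in shifts, and their introns held 23.8% against 33.6%. The one-sided permutation p for a higher count was 1e-05, the smallest possible, for promoter windows, noncoding RNA genes and intergenic sequence, and 1.67e-05 after adjustment over the 5 classes. It was 1 for exons and for introns, where both counts (478 and 478) lay below the lowest values that shifts gave (483 and 572). The classes overlap, since a promoter window can reach into a neighbouring gene.

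**Figure D2:**
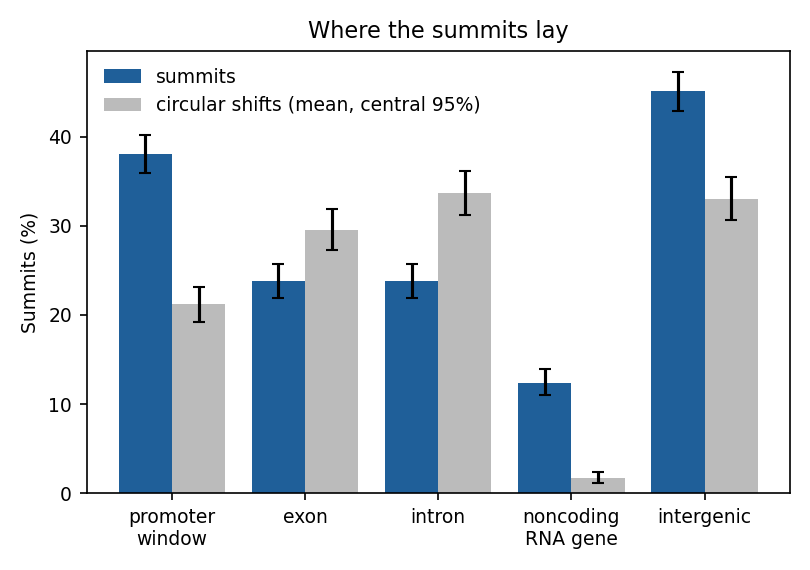
Percent of the 2010 summits in each class (blue, bars with exact 95% intervals) and mean percent over 100000 circular shifts (grey, with the central 95% of shifts). Promoter windows held 38.01% of summits against 21.2% in shifts, and noncoding RNA genes 12.4% against 1.75%.

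With the peaks of the main list, transfer RNA genes were the gene list bound most often: 253 of 612 tRNA genes, 41.3%, against 3.88% of all nuclear genes. The highest signals were at the divergent pair M02F4.t1 and M02F4.t2 on chromosome X (peak 3035985 to 3036320, signal 241), at T03E6.t1 on chromosome V (241) and at F15G9.t1 inside an intron of him-4 on chromosome X (225). In bound tRNA genes the nearest summit lay close to the start of the gene, at a median of 16 bp downstream of the 5′ end (quartiles -32 and 45), while in bound protein-coding genes it lay at a median of -252 bp. The odds ratio for tRNA genes was 20.1 (95% interval 17.01 to 23.8), with an adjusted p of 2.13e-190 in a two-sided Fisher exact test. It fell to 12.1 without replicate 2 and to 10.7 among the 500 strongest peaks. Genes for cytosolic ribosomal proteins came close, with 40.8% bound. Their odds ratio was higher than that of tRNA genes without replicate 1 (20.6 against 17.2) and without replicate 2 (17.8 against 12.1). These odds ratios have different backgrounds, all protein-coding genes and all nuclear genes, so their order is not a like for like comparison.

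Other short RNA genes were bound more often as well, and piRNA genes less often. Of 346 snoRNA genes, which guide modification of ribosomal RNA, 86 were bound (24.9%, odds ratio 8.55, Fisher exact adjusted p = 4.93e-43). The strongest, C06A1.9, K11H12.12, K11H12.13 and Y24D9A.9, had their summits in the windows of cdc-48.1, rpl-15 and rpl-7A, so that the snoRNA genes and these protein-coding genes cannot be separated. Of 129 genes annotated as snRNA genes, 16 were bound (odds ratio 3.53, Fisher exact adjusted p = 0.000172), among them the SL2 spliced leader genes sls-2.4 (signal 313), sls-2.1 (272) and sls-2.2 (229). The miRNA genes had 20 of 261 bound (odds ratio 2.07, Fisher exact adjusted p = 0.0123), led by mir-80 with a signal of 174, mir-354 with 174 at a summit shared with rps-20 and ekl-4, and mir-52 with 144. piRNA genes were bound in 122 of 15363 cases (0.794%, odds ratio 0.141) and pseudogenes in 24 of 2128 (1.13%, odds ratio 0.273), with Fisher exact adjusted p of 1.11e-162 and 7.28e-14. The background of 46890 nuclear genes includes these rarely bound piRNA genes, which raises the odds ratios of the other lists tested against it. A background without them was not tested, so the miRNA call in particular may depend on it. Leaving out 1 library moved the odds ratio of snRNA genes to 6.28 (without replicate 1) and 5.58 (without replicate 2), and that of piRNA genes to 0.0899 and 0.0919. The snRNA call ended when genes that shared a summit with another gene were left out (odds ratio 1.42, Fisher exact adjusted p = 0.940), and the miRNA call ended there, in each single-library list and among the stronger peaks.

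Among protein-coding lists, genes for cytosolic ribosomal proteins were bound most often. Of 76 such genes, 31 were bound (40.8%, against 4.45% of all protein-coding genes), with an odds ratio of 15.3 (95% interval 9.70 to 24.3) and an adjusted p of 2.42e-21 in the Fisher exact test. Besides rpl-3 and rpl-15, rpl-20 (signal 447) and rpl-35 (398) led this list, and the nearest summit lay at a median of -284 bp from the 5′ end of the bound members. Translation factors, with the lowest odds ratio of the 6 protein-coding lists bound more often, had 8 of 39 bound (odds ratio 5.58, Fisher exact adjusted p = 0.00101), led by iff-2 (308), eif-3.C (192) and eef-2 (187), whose summit lay in its 5′ UTR. Genes for mitochondrial ribosomal proteins did not pass, with 5 of 66 bound, among them mrpl-23 with a signal of 119.2.

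Chaperone, splicing, chromatin and respiratory chain genes were also bound more often than other protein-coding genes. Of 51 heat shock protein genes, 13 were bound (odds ratio 7.44, Fisher exact adjusted p = 1.57e-06), led by hsp-1 (signal 343), dnj-13 (329), hsp-60 (259) and hsp-110 (238), the last at a summit shared with the proteasome gene rpn-3. The spliceosome list had 10 of 38 bound (odds ratio 7.74, Fisher exact adjusted p = 2.48e-05), led by prp-19 (141) and the neighbours rsp-1 and rsp-2, which share a summit (118). Chromatin and SynMuv genes had 10 of 45 bound (odds ratio 6.19, Fisher exact adjusted p = 0.000112), with lin-54 (281), lin-9 (178) and the acetyltransferase gene hat-1 (164) behind cbp-1. The summit at lin-54 was shared with the ribosomal protein gene rpl-12, and that at hat-1 lay in an intron of another gene. The respiratory chain list had 10 of 47 bound (odds ratio 5.86, Fisher exact adjusted p = 0.000151), led by cox-5A (398), atp-1 (288) and cox-5B (226). The odds ratio of translation factors rose to 8.68 without replicate 2, and that of chromatin genes to 9.34 without replicate 1. The spliceosome call was lost among the 500 strongest peaks and in the list of replicate 2 alone (odds ratio 2.37, Fisher exact adjusted p = 0.390), and the translation factor call when genes sharing a summit were left out (2.39, Fisher exact adjusted p = 0.529).

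Chemoreceptor and C-type lectin genes were bound less often than other protein-coding genes. Of 1365 chemoreceptor genes, 8 were bound (0.586%, odds ratio 0.119, Fisher exact adjusted p = 2.50e-17), and of 240 C-type lectin genes, 3 were (odds ratio 0.269, Fisher exact adjusted p = 0.0345). No member was bound of the lists of 47 synaptic genes, 53 epidermis and molting genes, 48 major sperm protein genes or 23 dosage compensation and sex determination genes, and none of these 4 lists passed the test. Other tissue lists did not pass either: the muscle list had 1 of 57 bound (atn-1, signal 72.6), the intestine list 1 of 40 (cpr-1, 77.1) and the germ line list 1 of 72 (atx-2, 120.2). Among transcription factor families, nuclear hormone receptor genes had 6 of 269 bound, with nhr-47 (153) and nhr-68 (146) ahead of nhr-49 (99.7). They passed as bound less often with the longer window only (odds ratio 0.381). Homeobox genes had 1 of 87 bound (ceh-43, 59.9, at a summit inside a tRNA gene). C2H2 zinc finger genes had 4 of 66, led by ztf-7 (201) ahead of zfp-3 itself. In all, 10 lists were bound more often than the background, 4 less often, and 31 of the 45 did not pass. Peaks from an untagged strain or from other tagged proteins were not analysed here, so sites that any such protein would give are not marked. The call for C-type lectins held in 4 of 9 alternatives, and no member was bound in either single-library list.

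**Figure D3:**
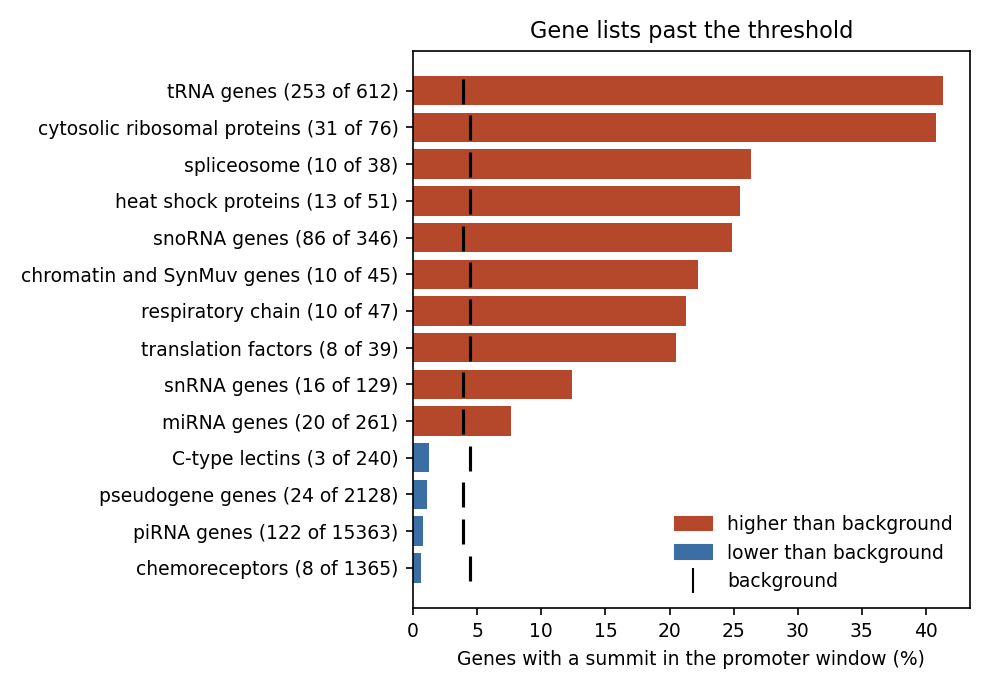
Percent of genes with a summit in the promoter window for the 14 lists past the threshold, with bound and total members in parentheses. Black ticks show the background, 4.45% of protein-coding genes or 3.88% of all nuclear genes, and tRNA genes stand highest at 41.3%.

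F-box, heterochronic and vitellogenin genes came closest without passing. The F-box and MATH/BTB families had 9 of 412 bound, with an odds ratio of 0.474 and an adjusted p of 0.0634 in the Fisher exact test. They passed as bound less often with the shorter and the longer promoter window (0.288 and 0.353). Their odds ratio was 0.307 without replicate 1 and 0.574 without replicate 2, not past the threshold in either. Of 25 heterochronic genes, which time larval development, 4 were bound: nhl-2 (signal 266), puf-9 (248), lin-46 (151) and ain-1 (85.8), with an odds ratio of 4.10 and an adjusted p of 0.0658 in the Fisher exact test. The list did pass among the stronger peaks and in each single-library list (odds ratios 8.16 without replicate 1 and 7.52 without replicate 2). Cell cycle and replication genes had 7 of 74 bound, led by pcn-1 (216), which encodes the sliding clamp PCNA, rfc-4 (124) and mcm-4 (113). The summit at rfc-4 was shared with eef-1A.1 and lay inside the miRNA gene mir-5549. The cell cycle list had a Fisher exact adjusted p of 0.116, and passed with the longer window (odds ratio 2.52, Fisher exact adjusted p = 0.0191). The vacuolar ATPase list, 3 of 21 bound with vha-20 (113) first, passed with the longer window (odds ratio 7.22) and in the other list of the series (6.64). Vitellogenin genes had 2 of 6 bound, vit-2 (79.0) and vit-5 (35.2), at summits in coding sequence (odds ratio 10.8, Fisher exact adjusted p = 0.0697); the list passed in 3 alternatives and had no bound gene in 4.

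Chromosome III carried more peaks than its length predicts and chromosome V fewer. Chromosome III held 362 peaks, 18.01% of the list (exact 95% interval 16.4 to 19.8%), against 13.7% of the base pairs, a ratio of 1.31 with an adjusted p of 2.01e-07 in a two-sided exact binomial test. Chromosome V held 321, 15.97% against 20.9%, a ratio of 0.765 (exact binomial adjusted p = 9.85e-08). The outer parts of the chromosomes, 66.7% of the base pairs, held 57.4% of the peaks (exact binomial adjusted p = 3.18e-17), so the central parts were richer in peaks. Chromosomes I (320 peaks), II (309), IV (335) and X (363) did not pass, with exact binomial adjusted p from 0.457 to 0.852. On X, 106 of the 363 peaks lay within 100 bp of a tRNA gene, since 276 of the 612 tRNA genes are on that chromosome. Without the peaks at tRNA genes, a choice made after seeing the data, X held fewer peaks than its length predicts (ratio 0.805, exact binomial adjusted p = 0.000175). With the share of protein-coding genes as the expectation, X held more (ratio 1.32, exact binomial adjusted p = 8.93e-08). In the list of replicate 1 alone, chromosome IV held fewer (ratio 0.813, exact binomial adjusted p = 0.0153).

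Sequences under the summits were rich in G and C and carried recurrent 6-mers. GACGCA was present within 50 bp of the summit in 182 of 2010 peaks (9.05%) and in the flanks of 35, a ratio of 5.20 with an adjusted p of 7.43e-23 in the exact McNemar test. ACGCGC was present at 144 summits and 20 flanks, a ratio of 7.20 (exact McNemar adjusted p = 4.29e-22). The other 3 of the 5 6-mers with the smallest p were AT-rich and fewer at summits: AAAAAT (593 summits, 928 flanks), TGAAAA (401 and 690) and AAAATT (498 and 798). Of 2080 6-mers, 463 were more frequent at summits and 261 less frequent, and the mean GC content was 44.1% at summits and 36.5% in flanks. Among 8-mers, AGACGCAG, which contains GACGCA, had the smallest p of those more frequent at summits, with 93 summits against 8 flanks (exact McNemar adjusted p = 1.65e-15).

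Peaks at promoters were somewhat stronger than the others. The 764 promoter peaks, led by rpl-3, F44E5.4 and tasp-1, had a median signal of 88.7 (quartiles 72.0 and 124), and the 1246 other peaks a median of 79.3 (quartiles 63.6 and 105). The difference in median log10 signal was 0.0485, with a two-sided permutation p of 1e-05, the smallest possible. Among the 500 strongest peaks the difference was 0.0170 (permutation p = 0.25), so it was not detectable there.

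The zfp-3 gene itself carried a peak upstream of its 5′ end. zfp-3 lies on the minus strand of chromosome X (1440360 to 1446643), and the main list held 1 peak within 5 kb of it, at 1446803 to 1447138, with a signal of 104.6 and its summit at -328 bp from the 5′ end in intergenic sequence. This peak ranked 595 in its list. Replicate 1 held 2 thresholded peaks there, the stronger with a signal of 61.8, and replicate 2 held none: its ranked list had a peak at the same place with a signal of 47.2 and a score of 559, below the authors' threshold of 830. Along the gene the ranked lists held weaker peaks in introns, coding sequence and the 3′ UTR, none of which passed the threshold. The site near zfp-3 was therefore past the threshold in the single-library list of 1 of 2 replicates. In the main list, which was thresholded over both libraries, it passed with a score of 1000.

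**Figure D4:**
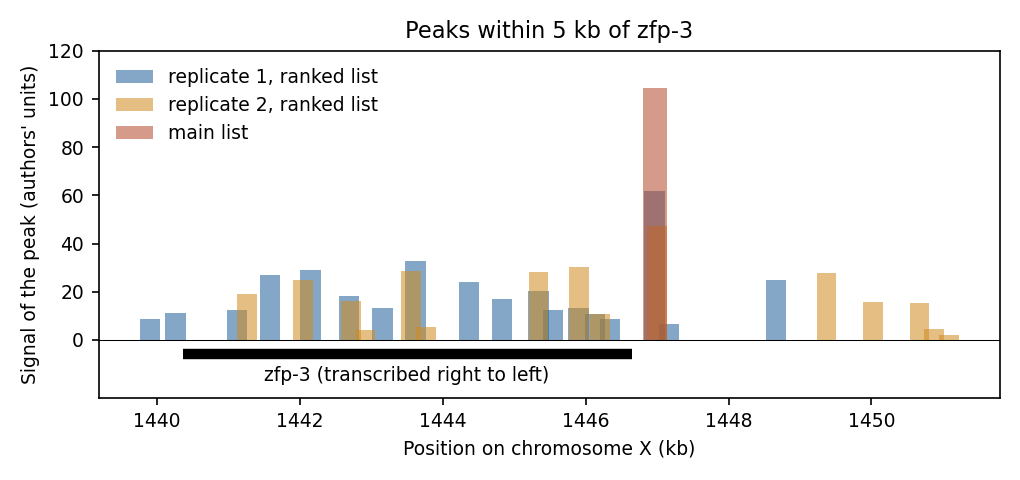
Peaks within 5 kb of zfp-3, plotted by position on chromosome X (kb) and signal in the authors' units, for the main list and the ranked lists of both replicates. Heights can be compared within a list only, and the peak of the main list, with a signal of 104.6, stands upstream of the gene's right end, where transcription starts.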

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

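All explanations in this part were weighed after the patterns had been seen, and the tests of tRNA clusters, GC content and the edge of the threshold were chosen after related values had been seen.

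Peaks in data outside the report drew attention because they passed the authors' IDR threshold and are absent from the main list. There were 49 such peaks in the ranked list, and the strongest, on chromosome X (15810941 to 15811276, intergenic), had a signal of 1440 (1439.9), above the highest signal of the main list, 778 at rpl-3. Copies of the sequence elsewhere in the genome go with this: a median of 89.7% of the 31-mers within 150 bp of these summits occurred elsewhere in the nuclear genome, against 0% in the main list (permutation p = 1e-05, the smallest possible). The edge of the threshold does not explain them, since their median -log10 IDR was 3.13 against 2.73 in the main list. Most of the 31-mers occurred elsewhere at 44 of the 49 peaks, but also at 94 peaks of the main list (4.68%). Copies alone therefore do not mark which peaks were left out. The authors may have removed some repeated regions, and whether ZFP-3 was bound there stays open. No biological explanation was tested.

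The binding of tRNA genes, 253 of 612, was weighed because tRNA genes occur in many copies and in clusters. Of the 140 tRNA genes whose exact sequence occurs once, 40 were bound (odds ratio 11.4, Fisher exact p = 1.41e-25), although genes with several copies were bound more often (45.1% against 28.6%). Such a gene can still differ little from another, and its window can hold the summit of a neighbouring tRNA gene. The test therefore cannot settle whether copies shared reads. Closeness to promoters of protein-coding genes is argued against by the 386 tRNA genes whose window overlaps none of them, of which 142 were bound (36.8%). Other nuclear genes with such windows, none of them protein-coding, were bound in 1.96% of cases (odds ratio 29.1, Fisher exact p = 1.01e-126). Because the comparison genes differ, this odds ratio cannot be set against the 20.1 for all tRNA genes. Clusters sharing a summit are argued against as the only source of the excess. There were 204 different summits within 100 bp of a tRNA gene, against a 95th percentile of 7 in circular shifts. The shifts do not measure how far shared summits raised the count of 253 bound genes. The tRNA call was kept with 1 gene per summit and with genes sharing a summit left out. A preference of any tagged chromatin sample for these genes also stays open, since peaks of other strains were not analysed here. No biological explanation could be set against it within 1 group.

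The 6-mer GACGCA, at 182 summits, was weighed because summits have a higher GC content than their flanks. Base composition stays open: GACGCA had the smallest p of the 6-mers more frequent at summits on chromosomes I to III, and on IV, V and X its ratio was 3.81 (95% bootstrap interval 2.43 to 6.58), against a 95th percentile of 3.26 for 219 other 6-mers with as many G, C and CpG, 4 of which had a ratio at least as high. Sequence of tRNA genes is argued against by a ratio of 4.91 once the peaks at tRNA genes were left out (172 summits, 35 flanks, exact McNemar p = 5.78e-24). Whether ZFP-3 itself or another factor at the same sites reads this sequence was not tested.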

How the results depend on the processing

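The alternatives were fixed before the data were examined, except leaving out peaks at tRNA genes, which was chosen after seeing the data. No paired analysis was possible because the labels give 1 group. The excess of summits in promoter windows (27.4 to 54.1% of summits, by window), the overlap of the replicates (51.6 to 68.8%) and the correlation of their signals (Spearman rho 0.741 with summits within 100 bp, and 0.402 over the ranked lists without the threshold) stayed past their thresholds under every alternative run. Of the 14 gene lists past the threshold, tRNA, snoRNA, piRNA, pseudogene, ribosomal protein, heat shock, respiratory chain, chromatin and chemoreceptor genes kept their call in all 9 alternatives, and C-type lectins and miRNA genes in 4 each. A total of 25 of the 45 lists passed in no setting.

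Leaving out 1 replicate gave 931 to 933 peaks and 285 to 322 6-mers more frequent at summits, against 463. The ratio of chromosome I was 0.970 to 1.03, not past the threshold, that of chromosome IV was 0.813 to 0.885 and passed without replicate 2, and leaving out either replicate left no vitellogenin gene bound (odds ratio 0). With the other list of the series the ratio of chromosome I was 0.986. The 1005 strongest peaks left vitellogenins at an odds ratio of 0 too, while the list passed with the other list of the series (14.1), the longer window (14.4) and genes sharing a summit left out (18.6). With the 500 strongest peaks, 213 6-mers passed, the difference in median log10 signal between promoter and other peaks fell to 0.0170 and no longer passed, X had a ratio of 0.973 and vitellogenins an odds ratio of 0; fewer peaks were tested. Windows of 25 bp gave 278 6-mers, and 232 8-mers passed. With gene numbers as the expected share, 5 of 7 regions passed in place of 3, II turned to 0.890 and IV to 1.01, and X rose from 1.02 to 1.32 and passed. Without peaks at tRNA genes IV turned to 1.01 and X to 0.805, and CGAACC no longer passed (1.65). Within 20 kb of zfp-3 there were 2 peaks in place of 1. The cause was not tested.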

Other observations

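The tests in this part were all chosen after the data had been seen. CGAACC was present at 92 of the 204 summits within 100 bp of a tRNA gene (45.1%) and in 6 of their flanks (ratio 15.3, exact McNemar adjusted p = 6.87e-21). GGTTCG, its reverse complement, is part of the internal promoter of tRNA genes that RNA polymerase III uses. These 204 peaks were selected for a tRNA gene near the summit, and their flanks were not. A high ratio for tRNA gene sequence at their summits follows from that choice and is no evidence on binding. The same choice bears on the other 6-mers at these peaks. Away from tRNA genes CGAACC was present at 51 of 1806 summits and 31 flanks, and did not pass (exact McNemar adjusted p = 0.0860). GCGCCA passed in both sets, at 19 summits and 3 flanks at tRNA genes and 129 and 24 elsewhere. ACGCGC (131 and 14) and GACGCA (172 and 35) passed away from tRNA genes only: at tRNA genes they had 13 summits and 2 flanks (exact McNemar adjusted p = 0.0534) and 10 and 4 (0.422). Differences between the sets were not tested. rpr-1, chosen after its value was seen, encodes the RNA of RNase P, which RNA polymerase III also transcribes in many animals. It had a summit in its window with a signal of 242.5, which also lay in an intron of a protein-coding gene. Among 20 rRNA genes, 0 were bound, and that list did not pass. Against 3.88% of all nuclear genes bound, 20 genes are too few to show that rRNA genes were bound less often. The main list also left out some peaks in repeated sequence, and whether any of these lay at rRNA genes was not tested. The share of tRNA genes bound was 48.9% on chromosome X, 47.4% on II, 43.8% on III, 37.9% on I, 29.6% on IV and 21.8% on V, and was not tested. Peaks at tRNA genes had a median signal of 91.4 and the others 81.0.

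Some 8-mers were more frequent at the strongest sites than at weaker ones. Of 4832 8-mers compared, 69 were more frequent among the 200 strongest peaks than among the 1810 others (Fisher exact tests, Benjamini-Hochberg adjustment); with 200 peaks, 8-mers this rare could hardly pass as less frequent. GTTGAATA had the smallest p, at 15 of the 200 strongest (7.50%) and 9 of the others (0.497%, Fisher exact adjusted p = 9.10e-07), followed by ATTCAACG (14 and 7) and TCAGCCAA (14 and 8). The 15 sites include those beside K08F11.7 (signal 734), mog-4 (578), K07D4.1 (549) and rpa-2 (519). A candidate explanation is a repeated element: in these 15 sites a median of 48.7% of the 31-mers within 150 bp of the summit occurred elsewhere in the genome, against 0% in the other 185 (permutation p = 1e-05, the smallest possible). Copies of such an element may be bound, or may gather reads that belong to other copies; the lists do not separate the 2.

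The main list held 74 peaks with a signal under 20, down to 2.00. Of these, 72 lay within 500 bp of a peak at least 3 times as strong, against 32 of the 1936 others (1.65%). A weak peak meets this rule more easily than a strong one, so these shares are not like for like.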
